A study of Homo sapiens with 9 samples.

How the data were processed

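Poly(A) RNA was sequenced from 9 libraries of H9, an established human embryonic stem cell line, at day 2 of a differentiation protocol. Per the labels, cells were grown on Matrigel in E8 medium and received CHIR for 2 days together with doxycycline, which induced a short hairpin RNA (shRNA). The labels name the compound only as CHIR. RNA was isolated with Trizol, and 0.5 µg entered a stranded TruSeq mRNA kit, per the labels' protocols. The genotype label put 3 libraries in each of 3 groups: a control hairpin (shCTL), a hairpin against ZEB1 (shZEB1) and a hairpin against ZEB2 (shZEB2). Hairpin sequences and the number of separately made cell populations per group are not given in the sources used here.

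The authors deposited a table of counts per gene, as whole numbers that were not normalised. STAR, RSEM and DESeq2 are named without versions or roles, per the submitters' processing notes. RSEM estimates need not be whole, so the deposited counts may have been rounded. Whether counting used the strand is not given in the sources used here, so overlapping antisense genes cannot be told apart with certainty, and reads of near-identical family members may have been split by estimate. The submitters' processing notes name the mouse build GRCm38, but all 58780 gene identifiers of the deposited table match human GENCODE release 29. Coordinates below are those of GENCODE 29 on GRCh38, and the build name in the notes was treated as an error of the record. The columns were mapped to samples through the titles in the labels, and 0 columns belonged to no sample.

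Total counts ranged from 31.4 to 38.5 M (1e6 counts) per library. Genes were kept by filterByExpr of edgeR with the group as design (minimum count 10, minimum total count 15), which left 17847 genes, 30.4% of the table. Counts were scaled by TMM. CPM values (counts per 1e6 counts of a library) are TMM-normalised, and log2 CPM used a prior count of 2. CPM values are given as mean ± SD of 3 libraries.

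Each comparison was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts as deposited. All 9 libraries entered 1 fit with the group as its only term. The threshold was a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. The standard error (SE) of a log2 fold change was taken from the fold change and its F statistic. With 3 libraries against 3, the exact permutation tests of single genes cannot give a two-sided p below 0.1. These tests permute libraries across experiments, so they ignore the pairing and include the spread between experiments. Ratios against a group with 1 to 3 counts carry a 95% exact interval that covers counting error only.

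The groups, tests, alternatives, naming rule and 24 gene lists were fixed before the data were examined. The lists covered pluripotency, primitive streak, presomitic, lateral plate and cardiac mesoderm, endoderm, neuroectoderm, neural crest, trophoblast, endothelium, epithelium, mesenchyme and muscle. They also covered Wnt, Nodal, BMP, FGF, Notch, cell cycle, p53, interferon, unfolded protein, hypoxia, HOX and mitochondrially encoded genes. Each list was tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, and p was adjusted over the 24 lists of a comparison. The same tests with an estimated correlation and with fry are given beside the calls, as are member counts adjusted over the list alone. Camera compares a list with the other genes, and fry asks whether the genes of a list move, on balance, in 1 direction.

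Named genes were ZEB1, ZEB2, up to 8 called genes with the largest rise and 8 with the largest fall, and up to 4 members of each list in order of unadjusted p. Called genes needed a mean of at least 2 CPM, groups that did not overlap and an ordinary gene symbol of a gene that is not a pseudogene. In the direct comparison of shZEB1 with shZEB2 the limit was 5 in each direction. Genes outside this rule were chosen after their values were seen: ZNF667-AS1, ZNF667, ZNF471, PCDHA10, HPRT1, CLC, FAR2P1, MAMDC4, CHCHD2, SPINK5, CDH1, ESRP1, EPCAM, ST14, DSP, MIXL1, TBXT and POU5F1 throughout, the shCTL levels of TBX6, NANOG and SOX2, the PCDHB5, CRB3 and CDH1 values of comparisons whose rule did not select them, and genes of the closing section that this rule does not give. A marker test of the EBF1 pattern and a further gene pair are not reported here.

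Replicates of 1 group were compared before averaging. The 9 pairs differed by far more than counting noise, with chi-square per degree of freedom from 14.42 to 118.4, so each library counted as 1 replicate. The labels state that each of 3 independent differentiation experiments gave 1 sample of each genotype, so the replicate number pairs the libraries. Deviations from the group means correlated between same-numbered shCTL and shZEB1 libraries with r of 0.64, 0.78 and 0.50. For shCTL with shZEB2 the values were 0.59, 0.14 and -0.31, and for shZEB1 with shZEB2 they were 0.51, 0.08 and -0.43. Library shZEB2-3 correlated instead with shCTL-2 (r = 0.60) and shZEB1-2 (r = 0.59). Whether shZEB2-2 and shZEB2-3 are numbered as performed is therefore open, and the values of shZEB2 given by experiment follow the numbers in the labels. These correlations are across genes, which are not independent. A fit with the experiment as a block was an alternative.

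Other alternatives set before the data were examined were size factors by the median of ratios, library totals alone, no count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean count of 50), DESeq2 (1.42.0), limma-voom, a fit of only the 6 libraries compared, a log2 fold threshold of 1, and leaving out each library in turn. The block combined with 6 libraries, with DESeq2, with limma-voom or with an estimated correlation was added after seeing the data. The gene and list tests were checked on simulated data with the real means, spread and library sizes. Of 100 genes changed by a log2 of 2, 65 were recovered for shZEB1 against shCTL among 17540 tested genes, 76 for shZEB2 against shCTL among 17522 and 75 for shZEB1 against shZEB2 among 17511. Of 100 genes changed by a log2 of 4, the same 3 comparisons recovered 91, 95 and 93. Genes called falsely numbered 11, 6 and 6 in these simulations. Each simulation held both sets of changed genes, which eases the adjustment of p, and no differences between experiments. Recovery in the real data may therefore be lower. The list test called 0 lists in unchanged simulated data of shZEB2 against shCTL and only the shifted list when the epithelial list was raised by a log2 of 1. Genes were simulated independently, so this does not test the list calls under the correlation seen in real lists. For called lists that correlation was estimated at up to 0.56 without the block and at 0.72 for p53 targets with it.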

Results

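The RNA of H9 human embryonic stem cells was profiled at day 2 of differentiation under CHIR, with a doxycycline-induced hairpin against ZEB1, against ZEB2 or a control hairpin. ZEB1 and ZEB2 encode zinc finger transcription factors known as repressors of epithelial genes. Each group held 3 libraries, 1 from each of 3 independent differentiation experiments. The shCTL libraries held 32.3, 32.2 and 31.4 M counts, the shZEB1 libraries 32.7, 35.5 and 38 M, and the shZEB2 libraries 33, 38.5 and 33.2 M. Of 58780 annotated genes, 17847 passed the count filter.

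The cells expressed genes of the primitive streak and early mesoderm in all groups. In shCTL, MIXL1 stood at 574 ± 184 CPM (SD, n = 3), TBXT at 425 ± 115 CPM and TBX6 at 111 ± 26.7 CPM. The pluripotency factor gene POU5F1 stood at 320 ± 76.4 CPM, whereas NANOG stood at 0.675 ± 0.139 CPM and SOX2 at 1.68 ± 0.563 CPM. A principal component analysis of log2 CPM separated libraries within groups as well as between groups. The first component carried 50.2% of the variance and set the experiment 2 libraries of shCTL (71) and shZEB1 (71.5) apart from those of experiments 1 and 3, which lay between -30.4 and -8.3. The second component, with 16.4%, held the shZEB2 libraries between 21.5 and 43.1 and all others between -30.6 and 8.81. The shZEB2 libraries were spread along the first component, from -80.1 in experiment 1 to 24.2 in experiment 3.

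**Figure D1:**
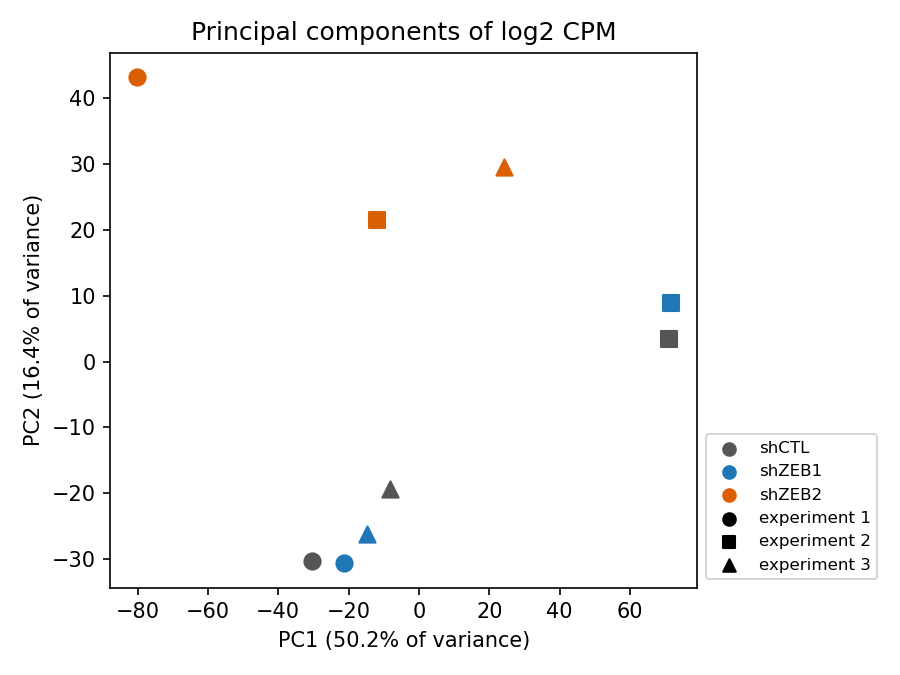
Principal components of log2 CPM for the 9 libraries, with PC1 (50.2% of variance) on the x axis and PC2 (16.4%) on the y axis; colour gives the group and shape the experiment. The experiment 2 libraries of shCTL and shZEB1 lie next to each other at high PC1, those of experiments 1 and 3 lie together at low PC1, and the shZEB2 libraries lie above them on PC2.

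The targeted genes were examined in every library. ZEB1 (ENSG00000148516.21, chromosome 10, 31318495 to 31529814) stood at 17.1, 34.5 and 21.7 CPM in shCTL and at 12.4, 21.7 and 14.8 CPM in shZEB1, in the order of the experiments. It was 27.3%, 37% and 31.8% lower in shZEB1 than in the shCTL library of the same experiment. The group means of 24.4 ± 9.02 and 16.3 ± 4.84 CPM overlapped in their spread, with a log2 fold change of -0.58 (SE 0.39, adjusted p = 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The two-sided exact permutation test, which ignores the pairing by experiment, gave p = 0.3, where the smallest possible p is 0.1. In the fit with the experiment as a block and only the 6 libraries compared, an alternative added after seeing the data, the log2 fold change was -0.57 with an adjusted p of 0.0481 by edgeR.

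ZEB2 (ENSG00000169554.19, chromosome 2, 144364364 to 144524583) stood at 70.8, 120 and 76.8 CPM in shCTL and at 43.6, 73.6 and 70.9 CPM in shZEB2. It was 38.4%, 38.4% and 7.61% lower within the 3 experiments. The group means were 89 ± 26.6 and 62.7 ± 16.6 CPM (log2 fold change -0.51, SE 0.26, edgeR adjusted p = 0.698), and the two-sided exact permutation test gave p = 0.3. Neither hairpin therefore moved its target past the threshold across all genes in the fit without a block. ZEB2 in shZEB1 stood at 95.7 ± 20.3 CPM (log2 fold change 0.11, edgeR adjusted p = 1). ZEB1 in shZEB2 stood at 16.5 ± 7.18 CPM (log2 fold change -0.57, edgeR adjusted p = 0.754), which was 50.4% and 46.1% below shCTL in experiments 1 and 2 but slightly above it in experiment 3.

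**Figure D2:**
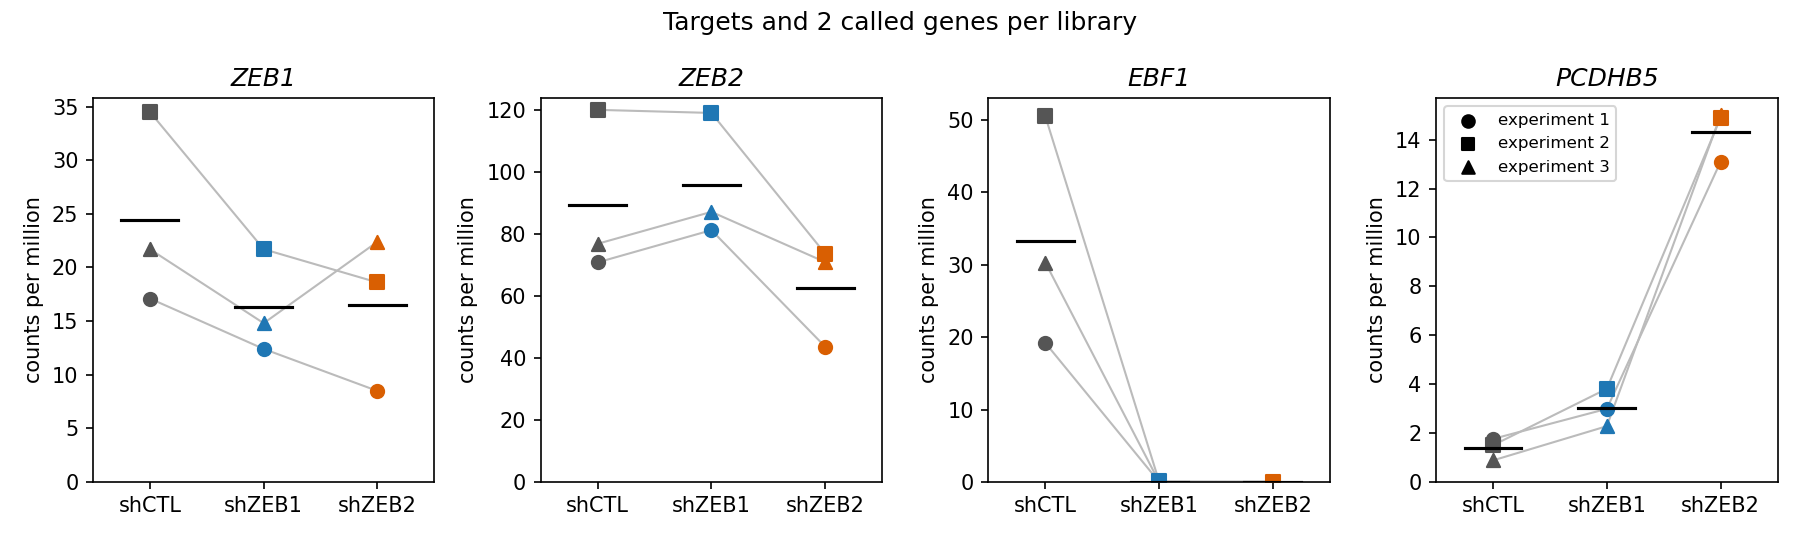
CPM of ZEB1, ZEB2, EBF1 and PCDHB5 in each library, with the group on the x axis, shape for the experiment, grey lines joining libraries of the same experiment and bars for the group mean. ZEB1 was lower in shZEB1 and ZEB2 lower in shZEB2 in all 3 experiments, EBF1 was near 0 in all 6 knockdown libraries, and PCDHB5 lay between 13.1 and 15 CPM in shZEB2.

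The comparison of shZEB1 with shCTL addressed which genes respond to the hairpin against ZEB1 at day 2. EBF1 (ENSG00000164330.16, chromosome 5, 158695916 to 159099761), a protein-coding gene for a transcription factor known from early B-cell development, was lower in shZEB1. It had 632, 1583 and 962 counts in the shCTL libraries (33.3 ± 15.9 CPM) and 0, 2 and 0 counts in the shZEB1 libraries. The ratio of shCTL to shZEB1 was 1748, with a 95% counting interval from 483 to 14439. EBF1 was the only gene past the threshold, with an adjusted p of 0.00421 by edgeR's quasi-likelihood test. The call was lost by edgeR without shZEB1-1 (adjusted p = 0.0587), shZEB1-2 (0.052), shZEB1-3 (0.0606) or shZEB2-3 (0.0533), and limma-voom gave EBF1 an adjusted p of 0.12. With only the 6 libraries compared edgeR called 0 genes, so EBF1 was lost there too.

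Several other genes had unadjusted p under 0.001 without passing the threshold in the fit of all 9 libraries without a block. The pseudogene FAR2P1 stood at 8.43 ± 1.4 CPM in shZEB1 and 0.911 ± 0.432 CPM in shCTL (edgeR adjusted p = 0.0731). It was also higher in shZEB2 than in shCTL by DESeq2 (4.67-fold, DESeq2 adjusted p = 2.04e-07). MAMDC4 stood at 21.7 ± 4.49 against 6.28 ± 0.488 CPM (edgeR adjusted p = 0.0731), and CHCHD2, which encodes a mitochondrial protein, at 158 ± 12.4 against 97.6 ± 8.03 CPM. CLC, the gene of a granulocyte galectin, stood at 1.53 ± 1.02 CPM in shCTL and 0.00978 ± 0.0169 CPM in shZEB1 (edgeR adjusted p = 0.51). SPINK5, a protease inhibitor gene, had a log2 fold change of -1.24 (SE 0.22). In total 0 genes were higher and 1 was lower by edgeR, 20 were higher and 8 lower by DESeq2, and 0 were called by limma-voom. At an unadjusted p under 0.05, edgeR counted 138 genes (56 higher, 82 lower), where 892 are expected by chance among 17847 if libraries are unpaired. Leaving out 1 library gave from 106 (without shCTL-3) to 279 genes (without shZEB1-1). In the fit with the experiment as a block and only the 6 libraries compared, added after seeing the data, edgeR called 23 genes, among them MAMDC4 (adjusted p = 0.00148), CLC (0.0153), FAR2P1 (0.0263) and CHCHD2 (0.0384), and counted 1109 genes at an unadjusted p under 0.05. With the block and all 9 libraries, only EBF1 was called and 219 genes were counted. The groups did not overlap for 561 genes, 3.14% of those tested, where chance gives 10% if libraries are unpaired. Same-numbered shCTL and shZEB1 libraries resembled each other (r of 0.64, 0.78 and 0.5). The values of 892 and 10% are therefore no fair yardstick here, and counts below them do not show fewer changes than chance.

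None of the 24 gene lists was called in shZEB1 against shCTL. Streak and mesoderm genes lay at similar levels in both groups: MIXL1 at 590 ± 221 CPM, TBXT at 426 ± 97.6 CPM and TBX6 at 132 ± 19.3 CPM in shZEB1. CDH1, the gene of the epithelial adhesion molecule E-cadherin, stood at 34.1 ± 15.3 CPM in shZEB1 and 34.1 ± 19.8 CPM in shCTL. Of 30 tested epithelial genes, 16 had positive and 14 negative fold changes, with a median log2 fold change of 0.01, and 0 passed the threshold over all genes or adjusted over the list alone. Among the members named by the rule, PKP3 had a log2 fold change of -1.25 (SE 0.66) and GRHL2 of 0.88 (SE 0.7). BMP targets had the lowest p of the lists, with a median of -0.16 and 12 of 13 genes below shCTL, including ID4 (log2 fold change -0.34, SE 0.3) and MSX1 (-0.17, SE 0.21). The camera adjusted p of that list was 0.164. Median and mean differed in sign for endoderm genes (0.06 and -0.07), muscle genes (0.03 and -0.04) and epithelial genes (mean -0.05), none of them called. In the interferon list, OAS3 had a log2 fold change of -1.55 (SE 0.61, unadjusted p = 0.032 by edgeR). The lowest adjusted p over the lists was 0.87 with an estimated correlation and 0.981 by fry, both from limma.

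The comparison of shZEB2 with shCTL addressed which genes respond to the hairpin against ZEB2. PCDHB5 (ENSG00000113209.8, chromosome 5, 141135218 to 141138625), a protein-coding member of the clustered protocadherins, which encode cell adhesion proteins, rose 10.3-fold. It stood at 14.3 ± 1.08 CPM in shZEB2 and 1.38 ± 0.452 CPM in shCTL (log2 fold change 3.37, SE 0.31, edgeR adjusted p = 0.0159). PCDHB5 stood at 3.03 ± 0.768 CPM in shZEB1, where it was not called. Every shZEB1 library (2.28 to 3.81 CPM) still lay above every shCTL library (0.881 to 1.76 CPM). EBF1 was again lower, with 0, 0 and 1 counts in the shZEB2 libraries against 3177 in shCTL, a ratio of 3472 with a 95% counting interval from 623 to 137178 (edgeR adjusted p = 0.00385). ZNF667-AS1 (ENSG00000166770.10, chromosome 19, 56477250 to 56500666), a long noncoding RNA gene, rose from 3 counts to 374, a ratio of 114 with a 95% interval from 39 to 556 (edgeR adjusted p = 0.0425). Its start overlaps the start of the opposite-strand gene ZNF667, and PCDHB5 belongs to a family of similar genes, so reads of both may have been shared. With the number of separately made populations per group not given, a difference unrelated to ZEB2 stays open for PCDHB5 and ZNF667-AS1.

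Other genes had low p-values without passing the threshold by edgeR, among them ZNF667 and ZNF471 beside ZNF667-AS1. ZNF667 stood at 5.36 ± 1.03 CPM in shZEB2 and 0.0607 ± 0.105 CPM in shCTL (edgeR adjusted p = 0.121), and ZNF471 at 1.58 ± 0.321 and 0.0202 ± 0.0351 CPM (edgeR adjusted p = 0.121). PCDHA10, of the separate alpha cluster of protocadherins, stood at 15.3 ± 5.65 and 2.7 ± 0.559 CPM (log2 fold change 2.5, SE 0.35, edgeR adjusted p = 0.121). CLC stood at 0.0203 ± 0.0351 CPM in shZEB2 and 1.53 ± 1.02 CPM in shCTL (edgeR adjusted p = 0.275, DESeq2 adjusted p = 0.00369). HPRT1, an X-linked gene for a purine salvage enzyme, had a log2 fold change of -0.63 (SE 0.09, edgeR adjusted p = 0.13). In total edgeR called 2 genes higher and 1 lower, DESeq2 134 and 43, and limma-voom 6 and 1. At an unadjusted p under 0.05, edgeR counted 1357 genes (842 higher, 515 lower), against 892 by chance. Leaving out 1 library gave from 852 (without shZEB2-1, below chance) to 1775 genes (without shZEB2-3). With the experiment as a block and all 9 libraries the count was 2652. Fits of only the 6 libraries compared, with 17290 genes tested, counted 1053 without the block and 1410 with it. The larger count of 2652 thus depended on including the shZEB1 libraries in the fit. The groups did not overlap for 2303 genes, 12.9%, where chance gives 10%.

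All 3 calls were sensitive to single libraries by edgeR. PCDHB5 had an adjusted p of 0.112 without shCTL-2, 0.0578 without shCTL-3, 0.0628 without shZEB1-1, and 0.0758, 0.142 and 0.105 without shZEB2-1, shZEB2-2 and shZEB2-3, at log2 fold changes from 3.13 to 3.44. EBF1 had 0.0577, 0.102 and 0.105 without shZEB2-1, shZEB2-2 and shZEB2-3. ZNF667-AS1 kept its call only without shCTL-1 and had adjusted p-values from 0.0755 to 0.217 without any of the other 8 libraries (shCTL-2 0.112, shCTL-3 0.217, shZEB1-1 0.137, shZEB1-2 0.0755, shZEB1-3 0.153, shZEB2-1 0.125, shZEB2-2 0.196, shZEB2-3 0.108). With the experiment as a block, its adjusted p by edgeR was 0.122. With only the 6 libraries compared, edgeR called 0 genes higher, so the calls of PCDHB5 and ZNF667-AS1 were lost and that of EBF1 was kept. With the block and 6 libraries, an alternative added after seeing the data, the edgeR adjusted p was 0.403 for PCDHB5 and 0.433 for ZNF667-AS1 and 0.0138 for EBF1.

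Of the 24 lists, epithelial genes had the largest median shift in shZEB2. CRB3, which encodes an apical polarity protein, stood at 1.72 ± 0.693 CPM against 0.136 ± 0.0494 CPM (12.4-fold). CLDN7, a tight junction claudin gene, stood at 17 ± 7.42 against 2.28 ± 1.11 CPM, AP1M2, a gene of basolateral protein sorting, at 13.2 against 3.88 CPM and the tricellulin gene MARVELD2 at 18.3 against 7.82 CPM. CDH1 stood at 145 ± 41.4 CPM in shZEB2 and 34.1 ± 19.8 CPM in shCTL, 4.25-fold higher (log2 fold change 2.09, SE 0.5). ESRP1, a regulator of epithelial splicing, had a log2 fold change of 2.37, the protease gene ST14 1.89 and EPCAM 1.25.

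Of 30 tested epithelial genes, 29 had positive fold changes in shZEB2, with a median log2 fold change of 1.45 and quartiles of 1.02 and 2.18. DSP, the desmoplakin gene, was the exception at -0.15. Over all genes 0 members passed the threshold by edgeR, 23 had an unadjusted p under 0.05 and 11 were called by DESeq2, all higher. Adjusted over the list alone, 19 rose by edgeR, led by CRB3, AP1M2 and MARVELD2, each at 0.0014, and CLDN7 at 0.00186; CDH1 was at 0.00877. For 21 of the 30 genes all shZEB2 libraries lay above all shCTL libraries. Chance gives 10% of genes for both directions together, and the share over all tested genes was 12.9%. Members of the list move together, so the 21 genes are not independent. The list was called higher by camera (adjusted p = 1.1e-22), but not with an estimated correlation of 0.56 (adjusted p = 0.573 with an estimated correlation) nor by fry (adjusted p = 0.0536). The mean log2 CPM of the list exceeded that of shCTL by 1.68, 2.44 and 0.62 within experiments 1, 2 and 3. In shCTL itself that mean was 3.29, 2.07 and 3.28 in the same order. Without shZEB2-1, the members that rose adjusted over the list alone numbered 11.

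**Figure D3:**
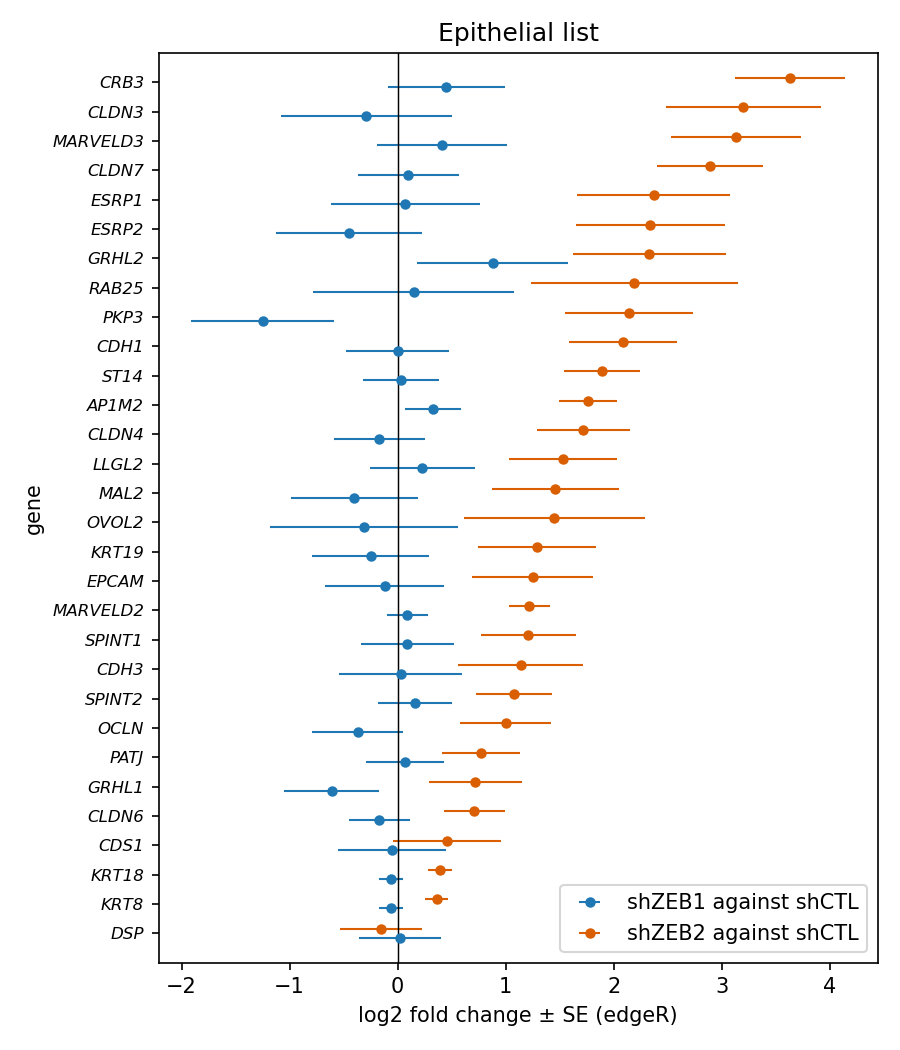
Log2 fold change of each of the 30 tested epithelial genes (y axis) with its SE, in shZEB1 against shCTL (blue) and shZEB2 against shCTL (orange). All genes but DSP lie above 0 in shZEB2, where the median is 1.45, and the shZEB1 values lie on both sides of 0, with a median of 0.01.

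Cell cycle genes were lower and p53 target genes higher in shZEB2 by camera. Of 22 cell cycle genes, 21 had negative fold changes, with a median log2 of -0.23. CDK1, which encodes the mitotic kinase, had a log2 fold change of -0.31 (SE 0.11), the spindle checkpoint gene BUB1 -0.30 (SE 0.12), the replication helicase gene MCM6 -0.34 (SE 0.13) and E2F1 -0.27 (SE 0.12). The list had a camera adjusted p of 0.000253, and adjusted p = 0.573 with an estimated correlation and 0.361 by fry. All 20 p53 targets had positive fold changes, with a median log2 of 0.42. CDKN1A, the gene of the cell cycle inhibitor p21, stood at 189 ± 150 CPM against 70 ± 11.7 CPM, and PHLDA3 (log2 fold change 1.35, SE 0.45), FDXR (0.97, SE 0.35) and the proapoptotic gene BBC3 (0.99, SE 0.4) followed. The camera adjusted p was 0.000342, and adjusted p = 0.573 with an estimated correlation and 0.443 by fry.

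The p53 shift rested on shZEB2-1 and shZEB2-3, with list means of 6.24 and 5.98 log2 CPM against 5.16 to 5.40 in shCTL, whereas shZEB2-2 stood at 5.08. CDKN1A was at 355, 63.9 and 148 CPM in these shZEB2 libraries in experiment order. Without shZEB2-3, the camera adjusted p of the p53 list was 0.0514. The cell cycle mean was lowest in shZEB2-1 at 6.81 log2 CPM, against 7.26 to 7.37 in shCTL and 7.18 and 7.23 in the other shZEB2 libraries. No member of either list passed the threshold over all genes or adjusted over the list alone by edgeR, where 4 cell cycle and 4 p53 genes had an unadjusted p under 0.05.

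The other 21 lists were not called in shZEB2 against shCTL by camera, with adjusted p from 0.0793 to 0.91. Pluripotency genes had a median log2 of 0.28, with SOX2 at 6.02 ± 4.44 CPM (log2 fold change 1.84, SE 0.66), KLF4 at 1.31 (SE 0.71) and DPPA4 at 0.32 (SE 0.16). Streak genes had a median of 0.18, with NKX1-2 at 1.89 (SE 0.84), FGF4 at 1.71 (SE 0.81) and CDX1 at 0.26 (SE 0.1). TBXT stood at 500 ± 32.7 CPM and MIXL1 at 548 ± 128 CPM in shZEB2. Presomitic genes had a median of 0.05 and lateral plate and cardiac genes of -0.19, including APLNR at -0.74 (SE 0.68). Neuroectoderm genes had a median of 0.32, with SOX3 at 2.81 (SE 1.23), POU3F2 at 1.32 (SE 0.39) and ZIC1 at 1.03 (SE 0.34). That list had an adjusted p of 0.169 by camera and 0.0434 by fry. Wnt targets, with a median of 0.09 and CCND1 at 0.38 (SE 0.12), had 0.425 by camera and 0.0434 by fry.

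Among the remaining lists in shZEB2, trophoblast and amnion genes had a median log2 fold change of 0.20, with TFAP2A at 2.3 (SE 0.76) and ELF3 at 1.03 (SE 0.42). BMP targets stood at a median of 0.27, with ID2 at 0.91 (SE 0.29). Notch genes had a median of 0.04, with HES4 at 1.54 (SE 0.41) and HES1 at 1.28 (SE 0.45). Mesenchymal genes had a median of -0.17, with the intermediate filament gene VIM at -0.17 (SE 0.13) and SNAI1 at -0.44 (SE 0.32). HOX genes had a median of -0.22, endothelial and blood genes -0.25, Nodal targets -0.20 and endoderm genes -0.09. For Nodal and endoderm genes camera pointed up (adjusted p = 0.372 and 0.695), opposite to their medians. Neural crest genes stood at a median of 0.07, muscle genes at 0.15, FGF targets at 0, unfolded protein genes at 0.04, hypoxia genes at 0.01 and mitochondrially encoded genes at -0.02. Interferon genes had a median of 0.19, and IFITM1 (log2 fold change 0.61, SE 0.14) was the only member of these 21 lists that rose adjusted over the list alone, with an adjusted p of 0.023 by edgeR.

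**Figure D4:**
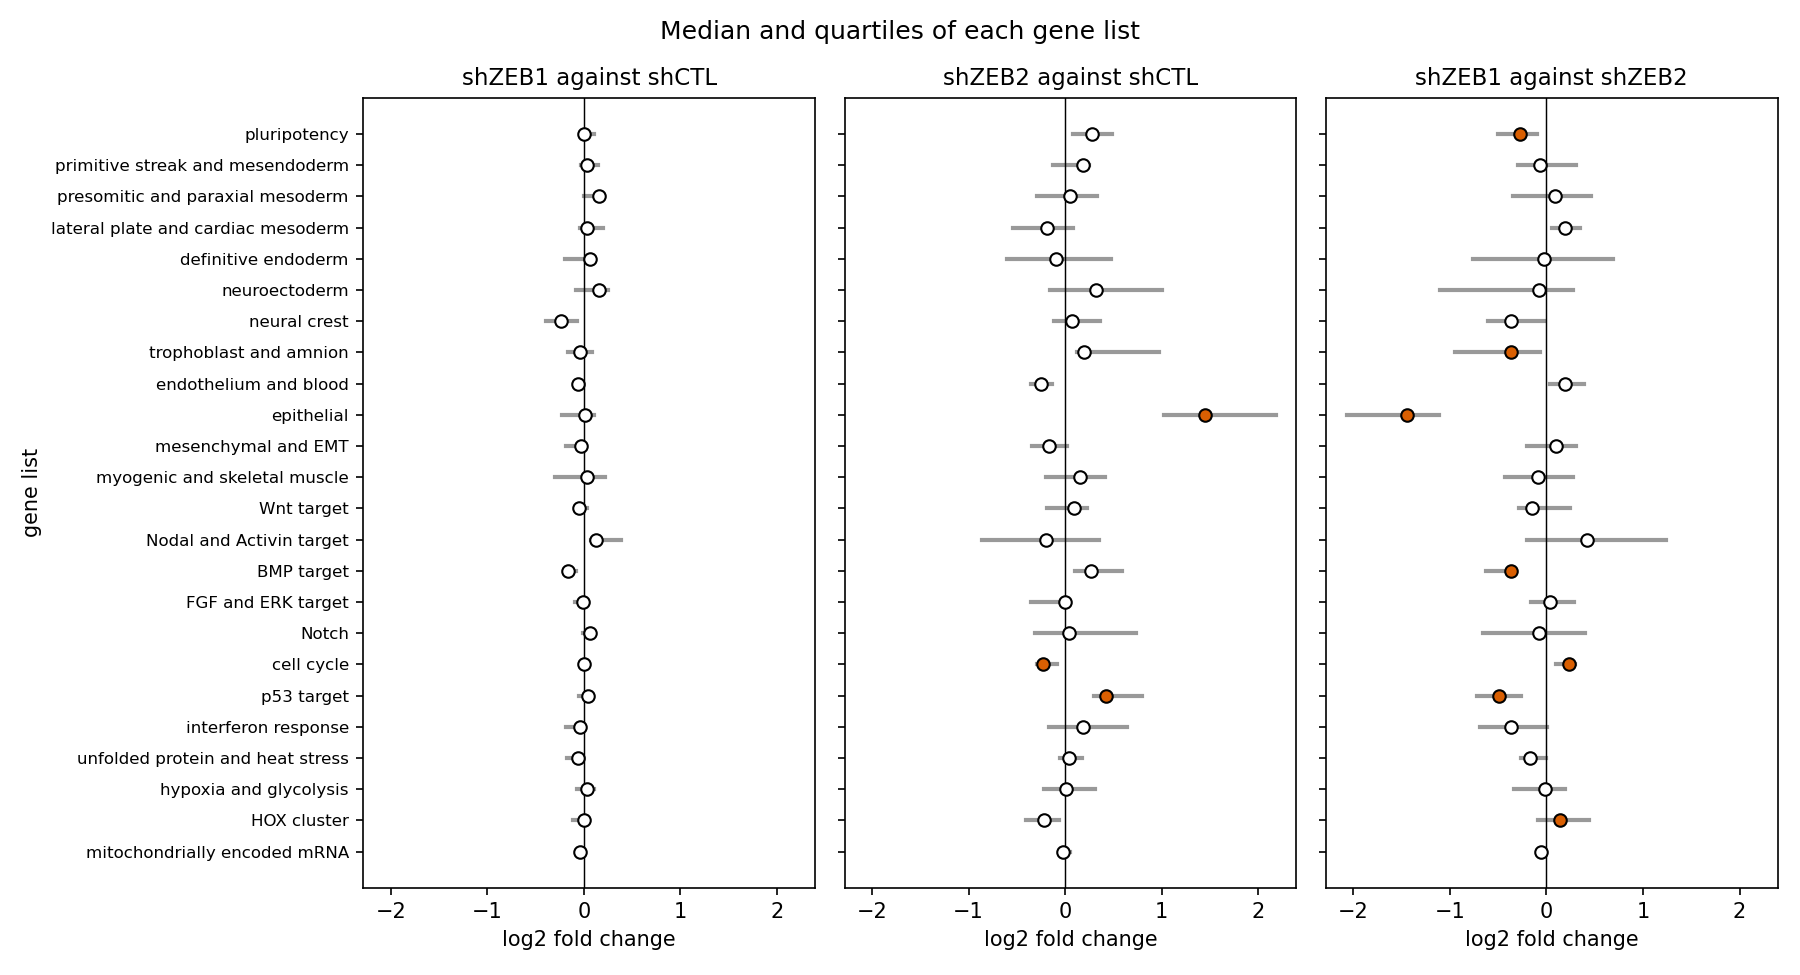
Median log2 fold change (points) and quartiles (bars) of the tested members of each of the 24 gene lists, per comparison; filled points mark lists called by camera with the preset correlation. The epithelial list stands at 1.45 in shZEB2 against shCTL and at -1.44 in shZEB1 against shZEB2, and no list was called in shZEB1 against shCTL.

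The direct comparison of shZEB1 with shZEB2 addressed how both knockdowns differ. Epithelial genes were lower in shZEB1: 29 of 30 had negative fold changes, with a median log2 of -1.44. CRB3 had a log2 fold change of -3.17 (SE 0.48), CLDN7 -2.79 (SE 0.49), AP1M2 -1.43 (SE 0.26) and MARVELD2 -1.13 (SE 0.19). Over all genes 0 passed the threshold by edgeR and 13 were called lower by DESeq2; adjusted over the list alone, 23 fell by edgeR. The camera adjusted p was 9.99e-24, and adjusted p = 0.415 with an estimated correlation. The members that fell adjusted over the list alone numbered 15 without shZEB1-2, 13 without shZEB2-1 and 15 without shZEB2-2.

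Cell cycle genes were higher in shZEB1 than in shZEB2 by camera (median log2 0.23, 21 of 22 positive, adjusted p = 9.12e-05, and adjusted p = 0.442 with an estimated correlation), with MCM6 at 0.41 (SE 0.13) and E2F1 at 0.36 (SE 0.12). All 20 p53 targets were on the lower side in shZEB1 (median -0.49, adjusted p = 0.000346, and adjusted p = 0.479 with an estimated correlation), including CDKN1A at -1.46 (SE 0.49). Without shZEB2-1 or shZEB2-3 the p53 list had an adjusted p of 0.0617 or 0.0583. BMP targets had a median of -0.37 (adjusted p = 0.0091, and adjusted p = 0.415 with an estimated correlation), with ID2 at -1.06 (SE 0.29) and ID4 at -0.99 (SE 0.3). Without shZEB2-3 this adjusted p was 0.184.

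Pluripotency genes (median -0.27, camera adjusted p = 0.0373), trophoblast and amnion genes (median -0.37, adjusted p = 0.0472) and HOX genes (median 0.14, adjusted p = 0.0373) lay nearer the threshold in shZEB1 against shZEB2. With an estimated correlation, the adjusted p-values were 0.415, 0.415 and 0.669. With the experiment as a block, the calls of pluripotency (camera adjusted p = 0.0503), trophoblast and amnion (0.0972) and HOX genes (0.0972) were lost. SOX2 had a log2 fold change of -1.57 (SE 0.65), NANOG -1.37 (SE 0.51), TFAP2A -2.82 (SE 0.78) and HOXB1 0.48 (SE 0.25). TFAP2A was the only trophoblast gene that fell adjusted over the list alone, with an adjusted p of 0.0406 by edgeR. The pluripotency call was lost without shZEB1-1 (0.165), shZEB2-1 (0.0609) or shZEB2-2 (0.255), the trophoblast call without shZEB2-3 (0.0933) and the HOX call without shZEB1-1 (0.107), shZEB2-1 (0.271, in the opposite direction) or shZEB2-2 (0.0692).

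The remaining 17 lists were not called in shZEB1 against shZEB2 by camera, with adjusted p from 0.0572 to 0.648. Nodal targets (median 0.42, camera adjusted p = 0.417) and FGF targets (median 0.04, 0.648) had a camera direction opposite to their medians, and endoderm genes (0.393) had a median of -0.03 and a mean of 0.26. Among the 17 lists, IFITM1 (log2 fold change -0.63, SE 0.14, adjusted p over the list alone 0.0188 by edgeR) and the skeletal actin gene ACTA1 (-1.58, SE 0.39, 0.0436) fell adjusted over the list alone. By fry, only the Wnt list was called (adjusted p = 0.00526), with CCND1 at -0.43 (SE 0.12) and DKK4 at -1.2 (SE 0.48). PCDHB5 had a log2 fold change of -2.24 (edgeR adjusted p = 0.0993). ZEB1 stood at a log2 fold change of -0.01, and ZEB2 at 0.61 (SE 0.26, edgeR adjusted p = 0.648), with all shZEB1 libraries above all shZEB2 libraries and a two-sided exact permutation p of 0.1, the smallest possible. Over all genes edgeR called 0, DESeq2 called 40 higher and 179 lower, and limma-voom called 0 higher and 4 lower. At an unadjusted p under 0.05, edgeR counted 1343 genes (417 higher, 926 lower), and groups did not overlap for 2094 genes, 11.7%, where chance gives 10%. The count of 1343, against 892 by chance, ranged from 840 (without shZEB2-1) to 1716 (without shZEB2-3) when 1 library was left out. With the experiment as a block and all 9 libraries it was 2448. Fits of only the 6 libraries compared, with 17293 genes tested, counted 1053 without the block and 1060 with it.

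Both knockdowns shared 1 called gene against shCTL, EBF1, lower in each, and 0 genes called in opposite directions. Lists drawn independently with these call counts would share 5.6e-05 genes lower in both. Across the 17847 genes, which are not independent, log2 fold changes in shZEB1 and shZEB2 correlated with r = 0.29, with the same sign for 59% of genes. In 100 simulations of unchanged groups against the same 3 controls, r averaged 0.50 and the same-sign share 66.7%, and 10 refits of such simulations called 0 genes in both. The simulations did not include the pairing of libraries by experiment. The covariance was 0.0372, against 0.0869 in the simulations, a difference of -0.0496. The 3 shCTL libraries are too few to split, so part of any overlap may come from the shared controls. Without any of the 3 shZEB1 or 3 shZEB2 libraries, 0 genes were shared by edgeR, and DESeq2 shared 11. Those of DESeq2 included FAR2P1, higher in each knockdown, and CLC, lower in each.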

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

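The tests of epithelial genes against single libraries, experiments and undifferentiated cells were chosen after the results were seen, as were the block fits combined with another setting; the other tests were written down before their values were seen, though after the patterns had drawn attention. Gene lists that differed in the direct comparison of shZEB1 with shZEB2 by camera drew attention as a difference between knockdowns. The epithelial list had a median log2 difference of -1.44 (adjusted p = 9.99e-24), with CRB3 and CLDN7 in front. The p53 target list differed by -0.49 (adjusted p = 0.000346), the cell cycle list by 0.23 (9.12e-05), the BMP target list by -0.37 (0.0091) and the trophoblast and amnion list by -0.37 (0.0472). The pluripotency list differed by -0.27 (0.0373) and the HOX cluster list by 0.14 (0.0373). The lowest adjusted p over these lists with an estimated correlation was 0.415.

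Other splits of the 6 libraries of each comparison were tested. With 10 splits per comparison the smallest share is 0.1, too large for a share under 0.05. For shZEB1 against shCTL, edgeR called 1 gene (EBF1) in the real split and at most 0 in the others, so 1 of 10 splits gave as many; lists numbered 0 and at most 8, and 10 of 10 splits gave as many. For shZEB2 against shCTL, the real split called 3 genes and 3 lists, the others at most 0 genes and 8 lists, and 1 and 9 of 10 splits gave as many. For shZEB1 against shZEB2, the real split called 0 genes and 7 lists, the others at most 0 and 8, and 10 and 2 of 10 gave as many. Among the 3 other splits that also part all 3 experiments, the highest list counts were 2, 8 and 8. The split of shCTL-1, shCTL-2 and shZEB1-2 from the rest called 8 lists where the real one called 0, and those of shCTL-1, shCTL-2 and shZEB2-3 or of shZEB2-1, shZEB2-2 and shZEB1-3 called 8 as well. For shZEB1 and shZEB2 against shCTL, another split thus called 8 lists, more than the 0 and 3 of the real split. In the direct comparison 8 was near the real 7. Experiment 2 of shCTL and shZEB1 and single shZEB2 libraries lay apart on the first principal component. Leaving out single shZEB2 libraries ended list calls, such as that of HOX genes in the direct comparison without shZEB2-1 (camera adjusted p = 0.271), but the cause of the list calls in the other splits was not tested. The preset correlation of 0.01 was below the 0.56 estimated for the epithelial list in shZEB2 against shCTL.

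EBF1 was present in all shCTL libraries and nearly absent from the 6 libraries of both knockdowns, and so was the low-count gene CLC (147 counts in shCTL, 1 in shZEB1 and 2 in shZEB2), which edgeR did not call in the fits of all 9 libraries. Reads of EBF1 passed to its paralogs EBF2, EBF3 and EBF4 are argued against, since these 3 genes together differed by -0.454 CPM in the knockdown libraries from shCTL. A difference between the cell populations that is unrelated to either target could give the same pattern, with all 6 knockdown libraries below the lowest shCTL library, and it cannot be told apart from an effect of the hairpins because the number of separately made populations per group is not given in the sources used here. Tested genes within 1 Mb on either side, from THG1L to PWWP2A, had log2 fold changes between -0.23 and 0.33 in both comparisons, and a shared response to both knockdowns stays open and untested.

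Epithelial genes such as CDH1, CRB3 and CLDN7 stood higher in shZEB2 than in shCTL and not in shZEB1. A single library is argued against as the whole cause, since the median log2 fold change was 1.03, 1.61 and 1.85 without shZEB2-1, shZEB2-2 or shZEB2-3; the highest camera adjusted p among these was 2.3e-16 at the preset correlation, but the list was not called at its estimated correlation of 0.56 (adjusted p = 0.573). No pairing of the libraries removes the difference, since the smallest difference in list mean over the 9 pairs of a shZEB2 and a shCTL library was 0.61. However, groups of 3 libraries fail to overlap in 10% of splits by chance, and the shCTL list means themselves ranged from 2.07 to 3.29 log2 CPM. The pairs therefore cannot decide how far differences between experiments contributed. A larger share of undifferentiated cells stays open: the pluripotency list had a median log2 fold change of 0.28 (13 of 17 higher, camera adjusted p = 0.0873), SOX2 and POU5F1 stood at 6.02 and 447 CPM in shZEB2 against 1.68 and 320 CPM, and TBX6 (22.7 CPM) and APLNR (176 CPM) were low in shZEB2-1, whereas the primitive streak list had a median of 0.18 (adjusted p = 0.173) and TBXT was not lower, so no list decides it. In shZEB2-3, SOX2 (1.58 CPM), POU5F1 (307 CPM) and APLNR (1520 CPM) lay within the shCTL range and TBX6 (155 CPM) above it. CDH1 (97.1 CPM) and CLDN7 (10.6 CPM) of shZEB2-3 still lay above every shCTL library. These are values of a single library, so the question stays open. Lower ZEB2, a repressor of CDH1 in other systems, is an untested biological hypothesis, and with the number of separately made populations per group not given in the sources used here, an effect unrelated to ZEB2 stays open as well. ZEB2 in shZEB2-3 (70.9 CPM) was at the level of shCTL-1 (70.8 CPM). ZEB1 averaged 16.5 CPM in shZEB2, near the 16.3 CPM of shZEB1, where epithelial genes were not higher. By library it stood at 8.48, 18.6 and 22.4 CPM in shZEB2-1, shZEB2-2 and shZEB2-3, against 12.4, 21.7 and 14.8 CPM in shZEB1. The similar means therefore do not decide whether lower ZEB1 goes with higher epithelial genes.

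X-linked genes were more frequent than others among the genes that separated shZEB1 from shCTL. At an unadjusted p under 0.001, 5 of 22 genes were X-linked (22.7% against 3.65% of tested genes, one-sided Fisher's exact p = 0.00101, among them PRPS1 and RBMX2, in both directions), a value that restates what drew attention, while shZEB2 against shCTL had 3 of 46 (Fisher's exact p = 0.226) and the direct comparison 4 of 72 (p = 0.261). A lost or gained active X copy is argued against, since the 651 tested X-linked genes had a median log2 fold change of -0.03 (quartiles -0.13 and 0.06). A silent copy would add little RNA, so this median cannot decide whether one was lost or gained. A different state of the X chromosome in the shCTL population may contribute, as groups did not overlap for 5.99% of X-linked and 3.04% of autosomal genes in shZEB1 and for 18% and 12.7% in shZEB2 (larger one-sided Fisher's exact p = 0.000103), where chance gives 10% if libraries are unpaired. The direct comparison, which has no shCTL library, showed the same excess (16% and 11.6%, p = 0.000611 by Fisher's exact test), so an excess of X-linked genes is not specific to shCTL, although these genes were mostly lower against shCTL (27 of 39 in shZEB1, 82 of 117 in shZEB2) and 60 of 104 were higher in the direct comparison, and genes on a chromosome are not independent.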

How the results depend on the processing

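The block combined with another setting, the other settings for the targets beyond those planned, and the counts of epithelial members under each setting were chosen after seeing the data. Size factors by the median of ratios, library totals alone and a log2 fold threshold of 1 kept every count of called genes; in each of the shifts that follow the cause was not tested unless fewer libraries or genes explain it by construction. For shZEB1 against shCTL, genes called higher numbered 5 with no count filter, 20 by DESeq2, 14 with the replicate block and 6 libraries and 24 with the block and DESeq2, and those lower 8, 0 by limma-voom, 0 with 6 libraries, 9 with block and 6 libraries and 10 with block and DESeq2, and 0 to 1 when 1 library was left out. For shZEB2 against shCTL, genes called higher numbered 1 with the replicate block, 12 without and 1 with the stricter filter, 134 by DESeq2, 6 by limma-voom, 0 with 6 libraries, 0 with block and 6 libraries, 289 with block and DESeq2 (20 of them epithelial) and 5 with block and limma-voom, with 0 to 3 when 1 library was left out; those lower numbered 43 by DESeq2, 94 with block and DESeq2 and 0 to 1 when 1 was left out. For shZEB1 against shZEB2, 3 were higher and 15 lower with no filter, 40 and 179 by DESeq2, and 99 and 371 (22 of them epithelial) with block and DESeq2, while limma-voom called 4 lower, 3 with the block. Unfiltered fits tested 32138 genes and the stricter filter 13871. The log2 fold change of ZEB1 in shZEB1 lay between -0.85 and -0.24 when 1 library was left out and was -0.57 with block and 6 libraries, past the threshold. ZEB2 in shZEB1 ranged from -0.09 to 0.39 when 1 library was left out. ZEB1 in the direct comparison, near 0, changed sign with the replicate block (0.03), limma-voom (0.05), block and 6 libraries (0.06), block and DESeq2 (0.04) and block and limma-voom (0.02), and ranged from -0.32 to 0.26 when 1 was left out; ZEB2 there passed the threshold with block and DESeq2 (0.63). Genes shared by both knockdowns numbered 11 by DESeq2 and 0 to 1 when 1 library was left out. Lists called in shZEB1 against shCTL numbered 0 to 1 up and 0 to 4 down when 1 library was left out. In shZEB2 against shCTL, an estimated correlation left 0 up and 0 down, as it did with the block. Fry called 0 down and 2 up, the neuroectoderm and Wnt lists, and none of the lists that camera called. By camera, leaving out 1 library gave 2 to 7 up and 1 to 3 down. In the direct comparison, an estimated correlation left 0 up and 0 down with or without the block, the block alone 1 up and 3 down, fry 0 up and 1 down, and leaving out 1 library 1 to 3 up and 2 to 9 down. The HOX cluster list in shZEB1 against shZEB2 reversed without shZEB2-1 (camera adjusted p = 0.271; range over single libraries left out 3.02e-07 to 0.271), CDH1 in shZEB1, near 0, turned to -0.01 with library totals, -0.36 without shCTL-2 and -0.38 without shZEB1-3 (range over single libraries left out -0.38 to 0.49), and DSP in shZEB2 to 0.23 without shCTL-2 and 0.08 without shZEB2-1 (range -0.39 to 0.23). Beyond the calls named with it in the results (ZNF667-AS1 and 3 lists of the direct comparison), the replicate block changed no other call. Of the alternatives for named genes and lists, 1653 kept direction and side of the threshold, 79 passed it, most by DESeq2, and 68 no longer did. The 1653 include genes called in neither fit, whereas the 68 come only from results called in the main fit. These counts therefore do not measure how well the calls held. At 31.4 to 38.5 M counts per library, genes such as CRB3 (3, 4 and 6 counts in the shCTL libraries) rest on few counts, so their fold changes are imprecise.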

Other observations

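The protocadherin test was written before its value was seen but after PCDHB5 and PCDHA10 had drawn attention, and all genes below were chosen after their values were seen. Several Nodal target and endoderm genes stood higher in experiment 2 than in the other experiments in shCTL and shZEB1 alike, whereas the mean log2 CPM of the primitive streak and mesendoderm list was 4.94 and 4.99 there and 4.89 to 4.98 in the other 4 libraries. Members of the streak list moved in opposite directions, with TBXT at 293 and 329 CPM against 427 to 524 CPM and MIXL1 at 787 and 845 against 447 to 479 CPM. Other lists differed too. The epithelial list mean was lower in experiment 2 (2.07 and 2.4 against 3.12 to 3.29 log2 CPM), and that of FGF targets was higher (6.06 and 6.12 against 4.64 to 4.97). CER1, a secreted Nodal and BMP antagonist of anterior endoderm, stood at 20.6 and 32.6 CPM in the experiment 2 libraries of shCTL and shZEB1, against 0.0304 to 0.329 CPM in their other 4 libraries. LEFTY2, a Nodal target, stood at 1.92 and 1.97 CPM against 0.0304 to 0.15 CPM, and the organizer gene GSC at 4.06 and 5.63 CPM against 0.576 to 1.74 CPM. CXCR4 (436 and 425 CPM) and the apelin receptor gene APLNR (2370 and 2490 CPM) were above the other libraries of these groups, at 175 to 238 and 922 to 1220 CPM. The mean log2 CPM of the Nodal and Activin target list was 3.64 and 3.92 there and between 0.80 and 1.38 in the other 4 libraries. In shZEB2-1, shZEB2-2 and shZEB2-3 the Nodal list mean was 1.78, 2.54 and 2.6, CER1 stood at 0.33, 2.3 and 1.64 CPM, GSC at 0.539, 1.24 and 1.34 CPM, CXCR4 at 48.5, 162 and 393 CPM and APLNR at 176, 891 and 1520 CPM. These values were not tested.

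Within shZEB2 the libraries spanned a wide range. HOX genes had a mean log2 CPM of 1.68, 2.75 and 3.76 in experiments 1, 2 and 3, against 2.95 to 3.16 in the other groups. SOX2 stood at 10.5, 6.02 and 1.58 CPM and POU5F1 at 644, 389 and 307 CPM in the same order. The mean of the epithelial list was 4.97, 4.51 and 3.9 log2 CPM. In experiment 1, shZEB2 thus combined the highest SOX2, POU5F1 and epithelial values of the 9 libraries with the lowest HOX and APLNR values.

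Clustered protocadherin genes on chromosome 5 as a whole were examined after PCDHB5 had been called in shZEB2. Over 44 tested genes of the 3 clusters, the median log2 fold change in shZEB2 was 0.14 and 30 were higher, with a camera p of 0.00201 and 0.0181 with an estimated correlation. The alpha cluster had a median of 0.68 (8 of 10 higher), the beta cluster 0.16 (13 of 14 higher) and the gamma cluster -0.07 (9 of 20 higher). In shZEB1 the camera p over the 44 genes was 0.873. The median of the beta cluster lay far below the log2 fold change of PCDHB5 (3.37), so a shift of the clusters as a whole does not account for that call; the set holds the genes that drew attention to it, and reads of these similar genes may have been shared.

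The rise of ZNF667-AS1 in shZEB2 came with higher ZNF667 and ZNF471 on either side of it on chromosome 19. ZNF667-AS1, ZNF667 and ZNF471 were at 3.55, 5.36 and 1.58 CPM in shZEB2, at 0.274, 0.408 and 0.068 CPM in shZEB1 and at 0.0304, 0.0607 and 0.0202 CPM in shCTL, so shZEB1 also lay above shCTL (edgeR adjusted p = 1 for each). In shZEB2, ZNF583, ZFP28, ZNF470 and ZNF71, farther out, had log2 fold changes of -0.06, 0.60, 0.04 and 0.13. The pseudogene ZNF542P stood at 2.06, 15.5 and 7.45 CPM in shCTL, shZEB1 and shZEB2. The 251 tested zinc finger genes of chromosome 19 had a median log2 fold change of 0 in shZEB2, and 126 of them were higher. Chromosome 19 genes as a whole had a median of 0.10 in shZEB2 (camera adjusted p = 0.000897 over 23 chromosomes, 0.353 with an estimated correlation).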
